A study of Mus musculus with 6 samples.

How the data were processed

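RNA-seq libraries of splenic CD4+ T cells from C57BL/6J mice with colitis induced by dextran sulfate sodium (DSS) were analysed. The 6 libraries form 2 groups of 3, from mice given Akkermansia muciniphila and from mice given phosphate-buffered saline (PBS). Total RNA was poly(A)-selected, per the labels' protocols, and all 6 libraries carry the batch label 1. How the CD4+ T cells were isolated is not given in the sources used here. The library descriptions name CD4 for both libraries numbered 1, CD5 for both numbered 2 and CD6 for both numbered 3, while the cell type entry of all 6 libraries names CD4. The group of each library was taken from its treatment entry.

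The authors deposited raw counts per gene as whole numbers, and FPKM values (values scaled for gene length and library size) rounded to 2 decimals. The genome build was GRCm39, per the submitters' processing notes. The aligner, the counting program, the gene annotation and the strand setting are not given in the sources used here. In 5248 genes with at least 500 counts in every library, the deposited FPKM values followed from the counts and a fixed gene length within 0.95%, after 1 factor per library between 0.973 and 1. The count table lists 54532 genes, of which 28006 had a count in any library. Of its identifiers, 54409 were found in GENCODE release M21, which was used for gene biotype and GC content. That release describes an older build than the 1 named by the submitters, so no genome positions are printed. Gene symbols are those of the deposited tables. Reads from near-identical genes and from genes on opposite strands could have been divided or merged in ways that cannot be seen from counts.

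The test used the counts as deposited. Genes were kept by filterByExpr in edgeR 4.0.16 (R 4.3.3) with a minimum count of 10 and a minimum total count of 15, which left 15138 genes. Libraries were scaled by the trimmed mean of M values (TMM), and the groups were compared by the robust quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. All 6 libraries entered 1 fit with no covariate. Log2 fold changes are Akkermansia over PBS, with standard errors (SE). Levels are counts scaled to library size with the TMM factors (CPM), given as mean ± SD of 3 libraries. A floor of 3 counts corresponds to 0.18 to 0.2 CPM.

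Gene lists, 48 in all with 916 entries, were fixed before the data were examined, as were the test, the groups, the alternatives in tool, filter, scaling, unit and pairing, and the rule for naming genes. Of 916 entries 915 were found in the tables, 34 of them under an older symbol. Of the 48 lists, 45 were compared with all other genes by limma camera (limma 3.58.1), two-sided, on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, adjusted over the 45 lists. The CD8 T cell list and the endothelial and stromal list had 2 tested genes each and were not compared, and the sex-linked list, with 4 tested genes, was only described. Camera with an estimated correlation and fry were run beside it. Members past the threshold were counted after adjustment over all genes tested, and again after adjustment over the list alone.

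The genes named were the 10 largest rises and the 10 largest falls among genes past the threshold with a mean of at least 1 CPM and groups that did not overlap. Predicted genes, pseudogenes and antigen receptor segments were left out of that part. Added to these were 11 landmark genes, and up to 4 members past the threshold from each list, those with the smallest p. In all, 161 genes fell under the rule, of which the text names a part. Any other gene named was chosen after its value was seen.

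The procedure was tested on simulated counts for the same 15138 genes and library sizes with 200 changed genes. The edgeR test recovered 42% of genes changed 1.5-fold, 58% of those changed 2-fold, 80% of those changed 3-fold and 90% of those changed 4-fold. Of its 150 calls, 10% were unchanged genes, above the nominal 5%. In the same simulation 15.9% of DESeq2 1.42.0 calls and 8.84% of limma-voom calls were unchanged genes. These shares come from a single simulation and depend on how many genes change. Far fewer were changed there than the 15.6% called in the data, so the shares do not carry over to the real calls.

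Alternatives were DESeq2, limma-voom, RLE size factors, other filters on low counts, protein-coding genes alone, edgeR's glmTreat against a fold of 1.5, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), a replicate block, and each library left out in turn. Scaling by library totals and offsets for gene length and GC content were added after the data were seen. Replicate pairs within a group differed by 4.47 to 19.9 times the sampling variance over at least 15072 genes, so no library was counted as a repeat of another. Figures were drawn with matplotlib.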

Results

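Gene expression was measured in splenic CD4+ T cells of mice with DSS colitis, in which a sulfated polysaccharide in the drinking water injures the colonic epithelium. One group of 3 libraries came from mice treated daily with Akkermansia muciniphila, a mucin-degrading gut bacterium, and the other 3 came from PBS-treated mice. The libraries are described as biological replicates and held 15032257 to 16677923 counts each, on average 15286431 ± 302224 (SD, n = 3) with Akkermansia and 16101669 ± 850225 (SD, n = 3) with PBS. Transcripts of the Y-linked gene Ddx3y were present in all 6 libraries, and of 4 tested Y-linked genes Ddx3y and Eif2s3y fell by 0.47 and 0.50 (log2, adjusted p = 0.00187 and 0.00279), while Kdm5d and Uty did not pass (0.06 and 0.05). The design asks how treatment with the bacterium changes the transcriptome of splenic CD4+ T cells during colitis.

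In splenic CD4+ T cell libraries, 8 of 17 NF-kB pathway genes and 8 of 19 T cell activation genes fell with Akkermansia, while 2 activation genes rose. Both lists were called lower by camera, but neither with an estimated correlation (adjusted p = 0.482 for each). Rel, an NF-kB subunit, fell from 331 ± 20.4 to 166 ± 7.89 CPM, and Tnfaip3, an NF-kB feedback inhibitor, fell from 3121 ± 448 to 1601 ± 162 CPM (SD, n = 3). Il10, an anti-inflammatory cytokine, and Il17f, a Th17 cytokine, also fell, while Foxp3, Tbx21 and Gata3, the lineage regulators of regulatory, Th1 and Th2 cells, did not pass the test. In the same libraries transcripts of other lymphocytes rose: Pax5, the B cell identity factor, from 26.3 ± 2.06 to 62.9 ± 8.06 CPM, and Cd8a, a CD8 T cell coreceptor, from 8.25 ± 1.15 to 38.8 ± 11.4 CPM (SD, n = 3). With Akkermansia 7 of 16 heat shock genes and 7 of 23 cholesterol synthesis genes rose and 1 of each fell, and 9 of 22 DNA replication and 5 of 22 G2 and M phase genes fell. None of these 4 lists was called with an estimated correlation (adjusted p = 0.555, 0.349, 0.482 and 0.555).

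By the edgeR quasi-likelihood test 1108 genes were higher and 1253 lower with Akkermansia, 15.6% of 15138 genes tested. A change of at least 2-fold was found in 164 of the higher and 243 of the lower genes, and the median absolute log2 fold change of all called genes was 0.51. The groups did not overlap in 5281 genes, 34.9% of those tested against 10% by chance. The coefficient of biological variation was 12.3%. The first principal component held 41.8% of the variance and parted the groups, with all 3 Akkermansia libraries between -29.0 and -27.7 and the PBS libraries between 24.4 and 31.6. The second component held 20.7% and ran within the PBS group, from -27.7 in PBS 3 to 37.1 in PBS 2. Without Akkermansia 1, Akkermansia 2, Akkermansia 3 or PBS 1, the counts fell to 647, 519, 535 and 679 higher and to 755, 623, 638 and 794 lower genes. Against a fold of 1.5 (glmTreat), 37 genes were higher and 50 lower.

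**Figure D1:**
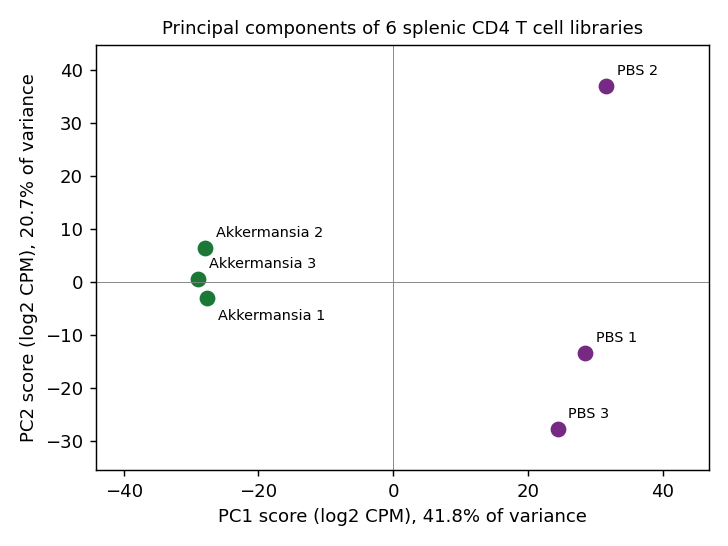
Scores of the 6 libraries on the first and second principal components of log2 CPM (horizontal axis 41.8% and vertical axis 20.7% of the variance; green, Akkermansia; purple, PBS). The 3 Akkermansia libraries lie together at -29.0 to -27.7 on the first component, and PBS 2 lies at 37.1 on the second.

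The largest rises included genes of other blood cells. Camp, the granulocyte antimicrobial peptide cathelicidin, rose by 3.46 ± 0.49 (log2, SE) from 0.674 ± 0.548 to 7.58 ± 2.37 CPM (SD, n = 3, adjusted p = 0.00167). Cd8a rose by 2.23 ± 0.21 (adjusted p = 0.000252), and the natural killer (NK) cell receptor genes Klra4, Klrc3, Ncr1, Klra8 and Klre1 rose by 2.58, 2.36, 2.22, 2.19 and 1.94. Lbp, which encodes a lipopolysaccharide-binding protein, rose by 2.82 ± 0.55 (adjusted p = 0.0203), and the list was completed by Slc41a2, a magnesium transporter (from 0.433 to 1.76 CPM), and S1pr3, a sphingosine 1-phosphate receptor (log2 fold change 1.98). Of these 10 genes, 6 belong to the marker lists of other cell types fixed beforehand. The Klra genes are near-identical copies whose reads the counting could have shared. The calls were lost for Lbp without any 1 of the Akkermansia libraries (adjusted p up to 0.0812), for Klrc3 without Akkermansia 1 or 3 (up to 0.0637) and for Slc41a2 without Akkermansia 1 or PBS 1 (up to 0.0623).

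The largest falls held no gene of those marker lists. Klf9, a Krüppel-like transcription factor induced by glucocorticoids, fell by 2.23 ± 0.18 (log2, SE) from 27.9 ± 4.71 to 5.92 ± 1.20 CPM (adjusted p = 1.75e-05), and Vegfa, an angiogenic factor, fell by 2.17 ± 0.29 from 7.36 ± 0.766 to 1.62 ± 0.672 CPM (SD, n = 3, adjusted p = 0.000432). Il17f fell by 3.05 ± 0.57 (adjusted p = 0.00357), on 4, 4 and 3 counts with Akkermansia and 15, 32 and 51 with PBS. Hbegf, an epidermal growth factor family ligand, fell by 2.01 ± 0.36 (adjusted p = 0.00273) and Sapcd2 by 2.01 ± 0.36 (adjusted p = 0.00287). The other 5 were Ston1 (-3.34), Sema3f (-3.15), Shisa7 (-2.62), Dusp8, a MAP kinase phosphatase (-2.38), and AC154912.5 (-2.16), with adjusted p from 0.021 to 0.0315. Each of these 5 lost its call in fits without some single libraries (adjusted p up to 0.128, 0.144, 0.114, 0.0965 and 0.108): Ston1 and Sema3f without any Akkermansia library or PBS 3, Shisa7 without any Akkermansia library or PBS 1, Dusp8 without Akkermansia 3 or PBS 1, and AC154912.5 without Akkermansia 1, Akkermansia 2 or PBS 1. With limma-voom Ston1, Sema3f and Shisa7 were not called (adjusted p = 0.129, 0.23 and 0.0901), nor was Ston1 with no filter on low counts (0.0649). On log2(FPKM + 1) Sema3f, Shisa7 and AC154912.5 were not called (0.115, 0.083 and 0.0635), nor were Sema3f and AC154912.5 on log2(FPKM + 0.1) (0.0781 and 0.0516).

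Among landmark genes of CD4+ T cells, Cd4 rose by 0.36 ± 0.07 (log2, SE) from 688 ± 31.9 to 884 ± 29.6 CPM (SD, n = 3, adjusted p = 0.00428). Il10 fell by 1.28 ± 0.25 from 10.8 ± 3.25 to 4.44 ± 1.15 CPM (adjusted p = 0.00539). The lineage regulators had log2 fold changes of 0.19 ± 0.12 for Foxp3 (adjusted p = 0.328), 0.37 ± 0.43 for Tbx21 (0.643), 0.09 ± 0.10 for Gata3 (0.581) and 0.08 ± 0.10 for Bcl6 (0.628), the regulator of follicular helper cells. Helper cell cytokines had values of -0.57 ± 0.44 for Ifng (adjusted p = 0.472), 0.29 ± 0.39 for Il4 (0.672) and -0.36 ± 0.65 for Il17a (0.766). The sign of Il17a turned without PBS 3 (0.87), and that of Bcl6 without PBS 1 (-0.0028).

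Markers of several other lymphocytes were higher with Akkermansia, with the most calls among those of B cells and larger medians among those of NK cells (1.94) and CD8 T cells (1.91). Of 21 B cell markers, 19 rose (19 adjusted over the list alone) and none fell, with a median log2 fold change of 1.17 (camera adjusted p = 8.35e-16, and adjusted p = 0.328 with an estimated correlation). Their summed level was 2978 ± 243 CPM with Akkermansia and 1679 ± 49.4 CPM with PBS (SD, n = 3). Spib, a B lineage transcription factor, rose by 1.63 ± 0.12 (adjusted p = 1.48e-05) and Pax5 by 1.25 ± 0.11 (adjusted p = 3.27e-05), whereas Ighm, the most abundant marker, rose by 0.25 from 660 to 785 CPM. Immunoglobulin and T cell receptor segment and constant genes, counted together, numbered 32 higher and 0 lower. How many were tested, and how many were of either kind, was not counted, so this is not a measure of B cells. Both CD8 T cell markers rose, Cd8b1 from 11.5 ± 1.67 to 34.7 ± 6.85 CPM (SD, n = 3, adjusted p = 9.11e-05), and 6 of 9 NK cell and innate lymphoid markers rose (6 adjusted over the list alone, camera adjusted p = 0.000227, and adjusted p = 0.328 with an estimated correlation). The 3 most abundant NK cell markers did not pass. Klrb1c had 8.36 CPM with Akkermansia and 9.30 with PBS, Fcer1g 16.3 and 17.9, and Tyrobp 12.2 and 10.9. The summed level of the NK cell list was 56.9 ± 4.40 CPM with Akkermansia and 42.8 ± 4.68 CPM with PBS (SD, n = 3).

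Of 17 cytotoxic effector genes 7 rose (12 adjusted over the list alone) and none fell, among them Gzma, a granzyme, by 1.93 ± 0.25 (adjusted p = 0.000977) and Prf1, perforin, by 1.09 ± 0.14 (adjusted p = 0.00051). For that list the camera adjusted p was 6.98e-05, and adjusted p = 0.477 with an estimated correlation. Dendritic cell markers rose in 5 of 12 genes (6 adjusted over the list alone, camera adjusted p = 0.000158, and adjusted p = 0.328 with an estimated correlation), but in 3 genes without Akkermansia 1, Akkermansia 3, PBS 1 or PBS 3. These 5 include Klrd1, an NK cell receptor gene also on the cytotoxic list, and Bcl11a, which B cells also express. Neutrophil and granulocyte precursor markers rose in 5 of 13 genes (8 adjusted over the list alone, camera adjusted p = 0.000221, and adjusted p = 0.555 with an estimated correlation), but in 3 without Akkermansia 1 or Akkermansia 2. The mean log2 level of the neutrophil list, relative to all libraries, was -1.60 in PBS 2, -0.47 in PBS 1 and 0.005 in PBS 3, against 1.13, 0.56 and 0.37 with Akkermansia. In the gamma-delta and NKT cell list 2 of 7 genes rose, Blk, which B cells also express, and Tcrg-C4 (3 adjusted over the list alone, camera adjusted p = 0.00269, and adjusted p = 0.328 with an estimated correlation), and 1 in each fit without 1 library, where Tcrg-C4 was not called (adjusted p up to 0.146). Mast cell and basophil markers had no call among 3 genes (1 higher adjusted over the list alone, camera adjusted p = 0.0337, and adjusted p = 0.471 with an estimated correlation), and the list was not called without PBS 1 (0.064) or PBS 3 (0.0615).

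Monocyte and macrophage markers did not differ as a list (camera adjusted p = 0.713), with a median of -0.04 and a mean of 0.0033, although 2 of 21 rose (2 adjusted over the list alone), Lyz2, lysozyme, by 1.11 ± 0.12 (log2, SE, adjusted p = 0.000197). The rises numbered 1 without Akkermansia 2, PBS 1 or PBS 3 and 4 without PBS 2. Erythroid markers had 3 falls and no rise in 18 genes (3 lower adjusted over the list alone, camera adjusted p = 0.136) and platelet markers 1 fall in 5 genes (camera adjusted p = 0.292). Plasma cell markers had an upward camera direction that did not pass (adjusted p = 0.0595), with 9 of 11 above 0, a median of 0.59 and summed levels of 954 ± 110 CPM with Akkermansia and 492 ± 222 CPM with PBS (SD, n = 3). Igha, the IgA heavy chain, had 461 ± 75.1 and 112 ± 55.9 CPM without passing (adjusted p = 0.0568), and the 1 plasma cell marker called was a fall, that of Irf4, which activated T cells also express. Irf4 was not called without any Akkermansia library, PBS 1 or PBS 3 (adjusted p up to 0.147), and the platelet fall was lost without Akkermansia 1, Akkermansia 3, PBS 1 or PBS 2. Lists became called in single fits: plasma cell markers higher without PBS 1 (0.0043), erythroid markers lower without Akkermansia 3 (0.0257) and platelet markers lower without Akkermansia 2 (0.0302). The 2 tested endothelial and stromal markers did not pass.

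**Figure D2:**
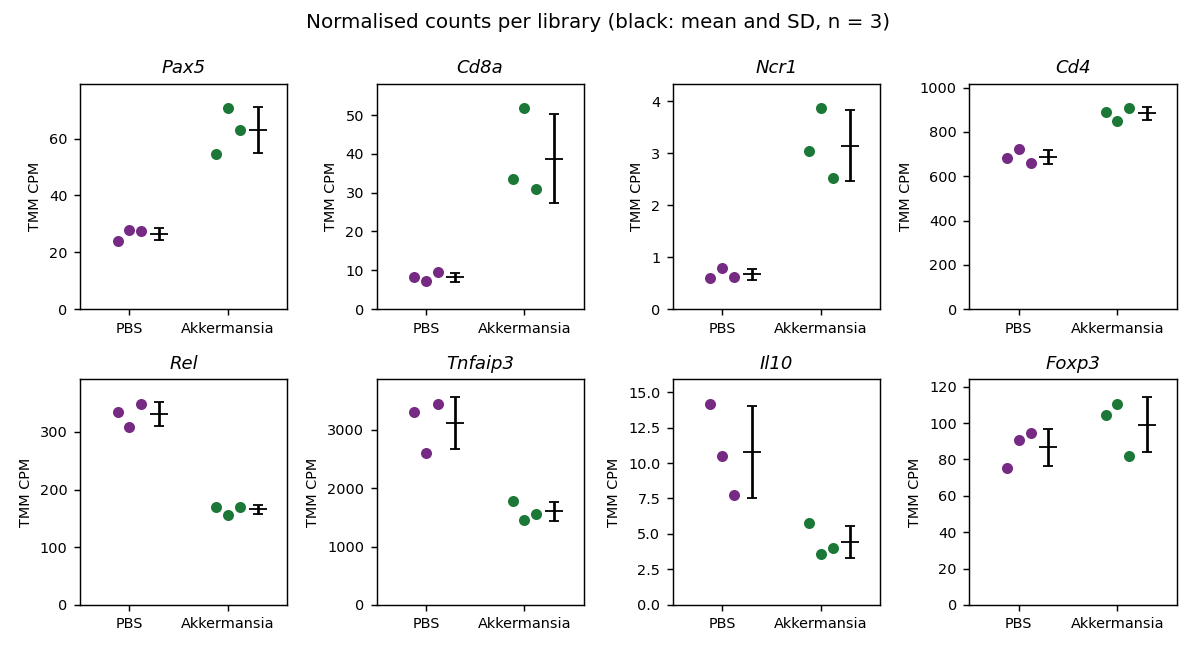
TMM-scaled CPM of 8 genes in each library (vertical axes from 0; purple, PBS; green, Akkermansia; black, mean and SD of 3 libraries). Pax5, Cd8a, Ncr1 and Cd4 are higher and Rel, Tnfaip3 and Il10 lower in all 3 Akkermansia libraries than in any PBS library, while the groups overlap for Foxp3.

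NF-kB pathway genes were lower with Akkermansia: 8 of 17 fell (9 lower and 2 higher adjusted over the list alone) and none rose. Rel fell by 1.00 ± 0.07 (log2, SE, adjusted p = 1.48e-05), Tnfaip3 by 0.96 ± 0.11 (adjusted p = 0.000282), Nfkbiz, an atypical IkB protein, by 0.81 ± 0.09 (adjusted p = 0.000127) and Birc3, an inhibitor of apoptosis, by 0.63 ± 0.07 (adjusted p = 0.000104). The camera adjusted p was 0.00633, and adjusted p = 0.482 with an estimated correlation. Apart from Rel, the NF-kB subunit genes did not pass: Nfkb1 (log2 fold change 0.11, adjusted p = 0.281), Nfkb2 (0.02, 0.899), Rela (-0.11, 0.404) and Relb (-0.19, 0.167). Immediate early genes, which respond within minutes to stimulation, fell in 7 of 22 cases (11 adjusted over the list alone, camera adjusted p = 0.000432, and adjusted p = 0.59 with an estimated correlation). Nfkbia, the NF-kB inhibitor IkB alpha, fell by 0.86 ± 0.09 (adjusted p = 7.66e-05) and Dusp5, an ERK phosphatase, from 501 ± 112 to 231 ± 20.8 CPM (SD, n = 3, adjusted p = 0.00757), while Fos and Jun had values of 0.04 ± 0.11 and 0.05 ± 0.15. This count was 4 without Akkermansia 1, Akkermansia 3 or PBS 3, 3 without Akkermansia 2 or PBS 1, and 13 without PBS 2. The mean log2 level of the immediate early list, relative to all libraries, was -0.11 in PBS 2, nearer to the Akkermansia libraries (-0.17, -0.25 and -0.23) than to PBS 1 and PBS 3 (0.38 each). Without PBS 2, 2 NF-kB genes rose. NF-kB genes moved in the libraries in which 19 of 21 B cell markers rose.

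T cell activation genes fell in 8 of 19 cases (10 adjusted over the list alone) and rose in 2, with a camera adjusted p of 0.0182, and adjusted p = 0.482 with an estimated correlation. Cd69, an early activation marker, fell by 0.54 ± 0.08 (log2, SE, adjusted p = 0.000945), and Il2, the T cell growth factor, from 1.85 ± 0.605 to 0.652 ± 0.113 CPM (SD, n = 3, adjusted p = 0.0298). Irf8, a transcription factor that B and dendritic cells also express, rose by 0.58 ± 0.08 (adjusted p = 0.000683). The number of falls was 5 without Akkermansia 1 or PBS 3, 2 without Akkermansia 2, 4 without Akkermansia 3 and 3 without PBS 1, and 1 gene rose without Akkermansia 3 or PBS 1. Regulatory T cell genes fell in 6 of 22 cases and rose in none (8 lower adjusted over the list alone), among them Itgb8, an integrin that activates TGF-beta, by 0.99 ± 0.16 (adjusted p = 0.0016), and Tnfrsf4, OX40, by 0.76 ± 0.15 (adjusted p = 0.00807). The regulatory list's camera adjusted p was 0.049, and adjusted p = 0.675 with an estimated correlation. It was not called without Akkermansia 2 (0.0811), Akkermansia 3 (0.27), PBS 1 (0.0751) or PBS 2 (0.107), with a filter of 1 CPM in 3 samples or with library totals. Its falls numbered 10 without Akkermansia 1 and 3 without Akkermansia 2, Akkermansia 3 or PBS 1.

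Cytokine feedback and STAT target genes fell in 4 of 17 cases (8 adjusted over the list alone, camera adjusted p = 0.0226, and adjusted p = 0.555 with an estimated correlation), including Pim2, a survival kinase, by 0.44 ± 0.07 (log2, SE, adjusted p = 0.00212). The list was not called without Akkermansia 3 (0.0611) or PBS 3 (0.0506), and its falls numbered 1 without Akkermansia 2 or Akkermansia 3, 2 without PBS 1 and 7 without PBS 2. Of the 7 genes on the aryl hydrocarbon receptor list 3 were tested and 2 fell (2 adjusted over the list alone, camera adjusted p = 0.0263, and adjusted p = 0.477 with an estimated correlation). These were Tiparp, a feedback repressor, by 1.54 ± 0.11 (adjusted p = 1.48e-05), and the receptor gene Ahr itself by 0.61 ± 0.16 (adjusted p = 0.0227). Il22 did not pass (-1.53, adjusted p = 0.393), and the targets Ahrr, Cyp1a1, Cyp1b1 and Nqo1 were removed by the filter on low counts. Apart from the receptor gene, Tiparp was thus the only member past the threshold. Without PBS 3 the list was not called (0.0765), and 1 gene fell without Akkermansia 2, Akkermansia 3 or PBS 3, where Ahr was not called (adjusted p up to 0.109).

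DNA replication and G2 and M phase genes had no member with a log2 fold change above 0. DNA replication genes fell in 9 of 22 cases (11 adjusted over the list alone), including Pcna, the replication clamp, by 0.66 ± 0.08 (log2, SE, adjusted p = 2e-04) and Mcm4, a replicative helicase subunit, by 0.46 ± 0.07 (adjusted p = 0.00147). The camera adjusted p was 6.98e-05, and adjusted p = 0.482 with an estimated correlation. The count was 4 without Akkermansia 2 and 5 without Akkermansia 3. Genes of the G2 and M phases fell in 5 of 22 cases (9 adjusted over the list alone), with a median of -0.53, among them Birc5, survivin, by 0.93 ± 0.25 (adjusted p = 0.0261). For these the camera adjusted p was 5.18e-05, and adjusted p = 0.555 with an estimated correlation. Their count was 1 without Akkermansia 2 or PBS 2, 0 without Akkermansia 3 and 3 without PBS 1, and without Akkermansia 3 the list kept its call (0.000226). The mean log2 level of the G2 and M phase list, relative to all libraries, was 0.09 in Akkermansia 1, beside 0.07 in PBS 3, against -0.51 and -0.40 in Akkermansia 2 and 3 and 0.20 and 0.54 in PBS 1 and 2. Birc5 itself was not called without Akkermansia 2, Akkermansia 3 or PBS 2 (adjusted p up to 0.116).

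Heat shock genes rose in 7 of 16 cases and fell in 1 (9 higher and 2 lower adjusted over the list alone), with a camera adjusted p of 0.0017, and adjusted p = 0.555 with an estimated correlation. Cochaperones of HSP90 were among the rises: Ahsa1 by 0.74 ± 0.08 (log2, SE, adjusted p = 0.000117), Chordc1 by 0.77 ± 0.09 (adjusted p = 0.000227) and Stip1 by 1.03 ± 0.12 (adjusted p = 0.000877). Hspa1a and Hspa1b, the inducible HSP70 genes, had values of -0.01 ± 0.34 and 0.36 ± 0.36 and did not pass. The fall was that of Bag3, a cochaperone of HSP70 (-0.42), which was not called without Akkermansia 2, Akkermansia 3, PBS 1 or PBS 3. Unfolded protein response genes went both ways, 5 up and 5 down of 18 (6 and 5 adjusted over the list alone, camera adjusted p = 0.506), with 2 up in every fit without 1 library except that without PBS 2. Of 14 integrated stress response genes 4 fell (7 adjusted over the list alone, camera adjusted p = 0.00142, and adjusted p = 0.328 with an estimated correlation), 2 of them subunits of the large neutral amino acid transporter, Slc3a2 by 0.77 ± 0.07 (adjusted p = 4.3e-05) and Slc7a5 by 0.60 ± 0.08 (adjusted p = 0.000573). Without Akkermansia 3 this count was 2.

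Cholesterol synthesis and uptake genes rose in 7 of 23 cases and fell in 1, Insig1 (9 and 1 adjusted over the list alone, camera adjusted p = 0.00269, and adjusted p = 0.349 with an estimated correlation). Sqle, squalene epoxidase, rose by 0.65 ± 0.10 (log2, SE, adjusted p = 0.0014). Insig1, a feedback inhibitor of the pathway, was not called without any 1 of the Akkermansia libraries. Fatty acid oxidation genes included 3 falls in 20 (3 adjusted over the list alone, camera adjusted p = 0.41), of which Cpt1a, the carnitine palmitoyltransferase that admits fatty acids to mitochondria, fell by 1.15 ± 0.11 (adjusted p = 7.65e-05). Glycolysis genes had 3 rises and 2 falls in 19 (3 and 2 adjusted over the list alone, camera adjusted p = 0.785), with the lactate transporter Slc16a1 falling by 1.15 ± 0.12 (adjusted p = 0.000117). Glycolysis had no rise by edgeR without Akkermansia 2, Akkermansia 3 or PBS 1, and 1 fall without these or Akkermansia 1. Fatty acid oxidation had 1 fall without Akkermansia 3. Nuclear oxidative phosphorylation genes fell in 2 of 63 cases (2 adjusted over the list alone, camera adjusted p = 0.0415, and adjusted p = 0.675 with an estimated correlation). That list was not called without Akkermansia 1 (0.275), Akkermansia 3 (0.077), PBS 1 (0.221) or PBS 2 (0.0975), with the replicate block (0.0505) or with offsets for length and GC content (0.145), and its falls numbered 1 without Akkermansia 1 and 4 without PBS 3.

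Cytosolic ribosomal protein genes were lower by a small and even amount: 78 of 79 lay below 0 with a mean log2 fold change of -0.22 (SD 0.12), and 10 fell (8 adjusted over the list alone). Rps27 fell by 0.46 ± 0.09 (log2, SE, adjusted p = 0.00675) and Rpl30 by 0.37 ± 0.08 (adjusted p = 0.00787). Their camera adjusted p was 7.35e-08, and adjusted p = 0.574 with an estimated correlation. The falls numbered 2 without Akkermansia 1 or Akkermansia 3, 6 without PBS 1 and 23 without PBS 3. Chromatin regulator genes rose in 5 of 19 cases (7 adjusted over the list alone), among them the histone H3K4 methyltransferases Kmt2d by 0.70 ± 0.09 (adjusted p = 0.000398) and Kmt2a by 0.62 ± 0.12 (adjusted p = 0.0081). For these the camera adjusted p was 0.00732, and adjusted p = 0.613 with an estimated correlation, and the count was 3 without Akkermansia 2 or Akkermansia 3 and 8 without PBS 3. The chromatin regulators list was not called with length and GC offsets (0.0543). Log2 fold changes rose with GC content over 10259 genes (Spearman 0.269, across genes, which are not independent replicates) and hardly with length (0.0628 over 10268 genes).

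Homing and adhesion genes rose in 4 of 18 cases and fell in 1 (9 and 2 adjusted over the list alone, camera adjusted p = 0.00633, and adjusted p = 0.555 with an estimated correlation). Itgb7, the beta chain of the gut-homing integrin, rose by 0.51 ± 0.07 (log2, SE, adjusted p = 0.000558) and Selplg, the P-selectin ligand, by 0.49 ± 0.07 (adjusted p = 0.000542). The fall, of the oxysterol receptor Gpr183 (-0.43), was not called without Akkermansia 2 or PBS 1. T cell receptor signalling genes rose in 6 of 27 cases and fell in 2 (9 and 3 adjusted over the list alone, camera adjusted p = 0.049, and adjusted p = 0.477 with an estimated correlation). Lck, the receptor-proximal kinase, rose by 0.33 ± 0.07 (adjusted p = 0.00606), and Cd28, the costimulatory receptor, fell by 0.87 ± 0.12 (adjusted p = 0.00163). The list kept its call without Akkermansia 2 (0.0302) and lost it without any other library (0.0628 to 0.0975). It was also not called with the replicate block (0.0787), with length and GC offsets (0.064), with RLE size factors, with library totals or with a filter of 1 CPM in 3 samples. Its rises numbered 3 without Akkermansia 2 and 2 without Akkermansia 3 or PBS 1, and its falls 4 without PBS 2.

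The remaining helper subset lists were not called. Th1 genes had 2 rises and 1 fall in 18 (camera adjusted p = 0.0766), with Cxcr6, a chemokine receptor, rising by 1.51 ± 0.20 (log2, SE, adjusted p = 0.00274). The Th1 list was called without PBS 1 (0.00134), where 5 members rose. Th2 genes had 1 rise and 3 falls in 11 (camera adjusted p = 0.41), Th17 genes 4 falls in 17 (0.772) and follicular helper genes 1 rise and 5 falls in 14 (0.118). Among these, Nfil3, a basic leucine zipper factor, fell by 1.74 ± 0.20 (adjusted p = 0.000778), Batf, a factor of Th17 and follicular helper development, by 0.55 ± 0.12 (adjusted p = 0.00748), and Btla, an inhibitory receptor, by 0.58 ± 0.09 (adjusted p = 0.00101). Adjusted over the list alone the counts were 2 and 1, 1 and 3, 1 and 4, and 1 and 5. The Th2 falls numbered 1 without Akkermansia 2, Akkermansia 3 or PBS 1, and the Th17 falls 2 without Akkermansia 2 or Akkermansia 3, with 4 Th17 rises without PBS 3. The follicular helper falls numbered 1 without Akkermansia 2 or Akkermansia 3 and 2 without PBS 1 or PBS 2, and that list was called lower without Akkermansia 1 (0.0451). Naive and quiescence genes had 3 rises and 1 fall in 18 (3 and 1 adjusted over the list alone, camera adjusted p = 0.353), with Klf2, a quiescence factor, rising by 0.57 ± 0.08 (adjusted p = 0.000634). Effector and memory genes, whose median was -0.05 and mean 0.06, had 2 rises and 1 fall in 19 (2 and 1 adjusted over the list alone, camera adjusted p = 0.577), with 4 rises without PBS 1 and 4 falls without PBS 3.

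Further lists that were not called were inhibitory receptors, with 1 rise and 3 falls in 13 (1 and 6 adjusted over the list alone, camera adjusted p = 0.0765), TGF-beta signalling, with 3 rises and 6 falls in 15 (4 and 7 adjusted over the list alone, 0.293), p53 and apoptosis, with 1 rise and 3 falls in 16 (2 and 5 adjusted over the list alone, 0.134), and autophagy and lysosome, with 1 rise and 6 falls in 23 (3 and 10 adjusted over the list alone, 0.0765). Inhibitory receptors were called without Akkermansia 1 (0.0466) or PBS 3 (0.0071), autophagy and lysosome without PBS 2 (0.0464), and p53 and apoptosis without PBS 2 (0.0374), where 5 of its genes fell. The autophagy falls numbered 1 without Akkermansia 1, Akkermansia 3 or PBS 1 and 2 without Akkermansia 2, the TGF-beta rises 1 without Akkermansia 3, and the inhibitory receptor falls 5 without PBS 3. None of 34 type I interferon genes passed by edgeR (camera adjusted p = 0.531), 0 had an unadjusted p under 0.05, and 0 passed with limma-voom or DESeq2, with a median of -0.33. That list was called lower without PBS 3 (2.95e-05, with 2 falls) and higher without PBS 2 (0.0243). Of 25 interferon gamma response genes 1 rose, Tap2 (0 adjusted over the list alone, camera adjusted p = 0.402), and the list was called higher without PBS 2 (0.000709, with 8 rises). Tap2 was not called without any 1 of the Akkermansia libraries (adjusted p up to 0.0814). Mitochondrially encoded genes had no call in 12 (camera adjusted p = 0.581), nuclear and stress RNAs 2 falls in 7 (3 adjusted over the list alone, 0.133, called without Akkermansia 2 at 0.0473), Malat1 by 0.48 ± 0.08 (log2, SE, adjusted p = 0.00258) and Gas5 by 0.32 ± 0.06 (adjusted p = 0.00606), and histone genes 2 rises in 6 (2 higher and 2 lower adjusted over the list alone), with a negative median (-0.32) and mean (-0.38) but an upward camera direction (0.882). The histone rises numbered 1 without any 1 of the Akkermansia libraries or PBS 2.

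**Figure D3:**
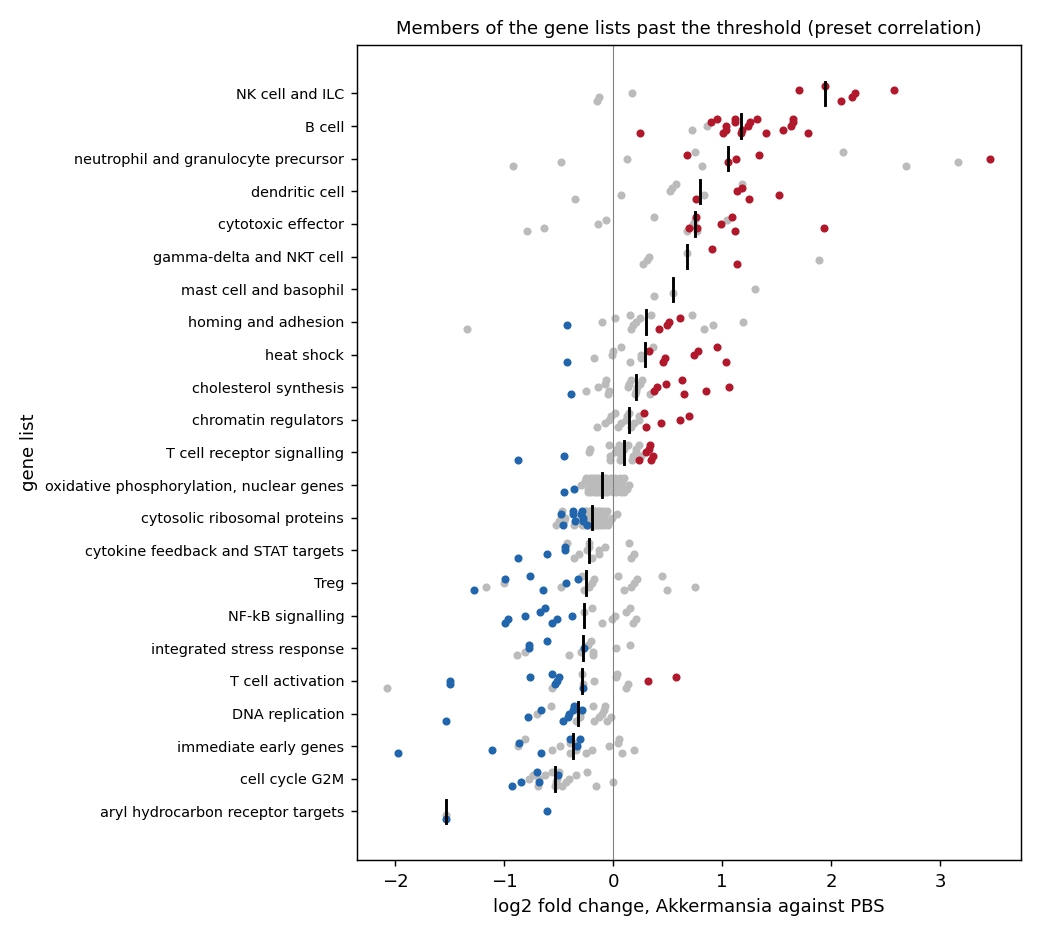
Log2 fold change (horizontal axis, Akkermansia over PBS) of each tested member of the 23 lists past the threshold by camera with the preset correlation (vertical axis, ordered by median). Red points rose and blue points fell at an edgeR adjusted p under 0.05, grey points did not pass, and black bars are medians. B cell markers have a median of 1.17 and G2 and M phase genes one of -0.53.

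Of the 45 lists tested, 23 were called with the preset correlation, 12 higher and 11 lower with Akkermansia. With the correlation estimated from the 6 libraries none was called (smallest adjusted p = 0.328), 6 had an unadjusted p under 0.05, and fry called 16. Of the 23, fry did not call 9: regulatory T cell genes, immediate early genes, G2 and M phase genes, nuclear oxidative phosphorylation, ribosomal proteins, cytokine feedback, homing and adhesion, chromatin regulators, and neutrophil markers. It called glycolysis and autophagy and lysosome genes (fry adjusted p = 0.0207 for each), which camera did not. Of the 153 named genes past the threshold, 96 were past it in each of the 6 fits that left out 1 library.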

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

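All tests here were chosen before the data were seen, except library totals, offsets for length and GC content, and the member counts of lists without single libraries. The numbers of genes higher and lower stayed within 1.5 times 1108 and 1253 with DESeq2 (1172 and 1277), limma-voom (1116 and 1192), RLE size factors, all filters on low counts, protein-coding genes alone, limma on log2(FPKM + 1) and log2(FPKM + 0.1) on the same genes, library totals and length and GC offsets (1050 and 1180). They fell to 37 and 50 with glmTreat against 1.5-fold, which asks for a larger change, and to 256 and 308 with limma on log2(FPKM + 1) over all 27971 genes above 0, a setting that tests more genes of low level. Leaving out 1 library gave 519 to 1287 higher and 623 to 1413 lower genes, with fewer samples in each fit. DESeq2 shared 2227 of the 2361 calls, limma-voom 2250, the offsets 1831 and the fit without Akkermansia 2 1113, and in no setting did a called gene keep its call with the opposite sign. The lists called numbered 0 with an estimated correlation, 16 with fry and 20 to 24 without single libraries, against 23, and mast cell and basophil markers lost their call with log2(FPKM + 1).

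Replicate numbers are shared by the groups, and the CD4, CD5 and CD6 of the library descriptions follow them. Beyond that, no source says what the numbers mark. Deviations from the group means correlated at 0.0846, 0.0774 and 0.0303 in libraries of the same number, below 0.1, although every library correlated best with its own number. With the replicate number as a block, 1205 genes were higher and 1333 lower and 23 lists were called, not the same 23: T cell receptor signalling (0.0787) and oxidative phosphorylation, nuclear genes (0.0505) lost their calls, and inhibitory receptors (0.0339) and plasma cell markers (0.0202) gained one. Of the called genes named in the report, Sema3f lost its call there (0.0517).

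Directions turned in results that were not called. Il17a changed sign with limma-voom (0.0951), log2(FPKM + 0.1) (0.0669) and without PBS 3 (0.867), and Bcl6 without PBS 1 (-0.00276). Leaving out 1 library gave -0.810 to 0.867 for Il17a and -0.00276 to 0.149 for Bcl6. Mean log2 fold changes turned for Th17 genes (0.031 with 1 CPM in 3 samples, 0.123 without PBS 3), effector and memory genes (-0.0492 without Akkermansia 1, -0.0500 without PBS 3), type I interferon genes (0.00103 without Akkermansia 1, 0.264 without PBS 2), interferon gamma response genes (-0.123 without PBS 3), mitochondrially encoded genes (0.0686 without PBS 2, 0.105 with length and GC offsets), monocyte and macrophage markers (-0.0053 without Akkermansia 1, -0.00927 without Akkermansia 2, -0.071 without PBS 1) and histone genes (0.0821 with log2(FPKM + 1)). Over the 6 such fits the ranges were -0.269 to 0.123 for Th17, -0.0500 to 0.184 for effector and memory, -0.583 to 0.264 for type I interferon, -0.123 to 0.296 for interferon gamma, -0.196 to 0.0686 for mitochondrially encoded genes and -0.0710 to 0.0516 for monocyte and macrophage markers. The cause was not tested. At this depth a floor of 3 counts, 0.18 to 0.2 CPM, limits what can be said of genes such as Il17f.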

Other observations

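Tests chosen only after the result was seen were those on the monocyte and macrophage list, on the spread of the B cell list and on the heat shock list, and the glucocorticoid medians without single libraries. Genes induced by glucocorticoids, a list drawn up after the first results but before it was tested as a list, were lower with Akkermansia. Its members Zbtb16, Ddit4, Dusp1, Il7r, Cxcr4 and Cdkn1a also belong to fixed lists, so their values were part of the first results. Of 14 tested genes 5 fell and none rose, with a median log2 fold change of -0.77 (camera p = 2.56e-05, adjusted over 4 such lists 5.12e-05, and p = 0.154 with an estimated correlation). Tsc22d3, encoding the glucocorticoid-induced leucine zipper, fell from 342 to 206 CPM (adjusted p = 0.000122), Irs2 from 299 to 108 CPM (adjusted p = 0.000489), and Per1, a clock gene with a glucocorticoid response element, from 619 to 318 CPM (adjusted p = 0.00875). Fkbp5, a feedback regulator of the receptor, stood at 67.2, 69.7 and 63.7 CPM in the Akkermansia libraries and at 314, 94.1 and 179 CPM in the PBS libraries (log2 fold change -1.55, adjusted p = 0.127). The median was -0.63 without PBS 1 and -0.88 without PBS 2, with 4 to 8 falls. Over the 7 genes that no other list holds the median was -0.73, and 2 of them fell.

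Interferon response genes varied mostly within the PBS group. The mean log2 level of the type I interferon list, relative to the mean of all libraries, was 0.89 in PBS 2, 0.13 in PBS 1 and -0.81 in PBS 3, against -0.36, 0.12 and 0.02 in the Akkermansia libraries. The short RNA Gm23935 had 35010, 16830 and 7134 counts in the PBS libraries and 3569, 4008 and 3406 in the Akkermansia libraries, and Lars2 had 10016, 4847 and 2038 against 1235, 1401 and 1186. An ex vivo dissociation stress list of 25 genes had 3 rises and 4 falls, with a median of -0.01 (camera adjusted p = 0.488). All of its genes belong to the fixed immediate early, heat shock or cytokine feedback lists. The immediate early list was called lower and the heat shock list higher, so this median mixes known changes and cannot decide on dissociation stress.

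Markers of other lymphocytes were higher with Akkermansia. A lower share of CD4 T cells that raised every other cell type alike would also raise monocyte and macrophage markers. Their list had a median of -0.038 where the B cell list had 1.17, a comparison chosen after these values were seen. Medians were 1.94 for NK cell, 1.91 for CD8 T cell, 1.05 for neutrophil and 0.79 for dendritic cell markers. Those of erythroid and platelet markers were -0.19 and -0.34, and Cd4 itself rose. Other cells need not rise alike, so an unequal change in cell shares is not excluded. More B cells in these libraries may account for the B cell part: 25 further B cell genes, none of them in the fixed list and 1 in another list, had a median of 0.80, all were above 0 and 19 rose, although Ighm and Igkc, among the most abundant B cell transcripts, had log2 fold changes of 0.25 (passing) and 0.72 (not passing, adjusted p = 0.219). Transcription of these genes by the CD4 T cells themselves cannot be told apart from other cells in bulk RNA, and the SD of the log2 fold changes over the B cell list was 0.362. Whether the spleen or the isolation supplied such cells is open, since a CD4 selection would remove B cells and its method is not given in the sources used here.

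Part of the immediate early and NF-kB genes fell with Akkermansia, the immediate early list standing near the Akkermansia level in PBS 2 (-0.11). If a general stress of cell isolation in the PBS samples raised heat shock genes too, these would be lower with Akkermansia. Their median was 0.29 higher with Akkermansia, a test chosen after that value was seen. Hspa1a and Hspa1b, the inducible HSP70 genes, did not pass (-0.01 and 0.36). A stress that leaves heat shock genes unchanged is not excluded. A large shift in time of day is argued against by the clock genes, of which 2 of 15 passed, Per1 and Nr1d2. Per2 stood at 0.05, Dbp at 0.14 and Arntl at -0.14. Ciart lay just short of the threshold (-0.53, adjusted p = 0.0506). Cry2 (-0.34, adjusted p = 0.143), Tef (-0.19, 0.151) and Clock (-0.20, 0.151) had the same sign, while 6 of the 15 lay above 0. A smaller shift is thus not excluded. Higher glucocorticoid exposure in the PBS mice may be part of the difference, since glucocorticoid targets had a median of -0.77. Nfkbia, Per1 and Klf9 are known to respond to the hormone but add no separate support. Per1 is already in that median, Nfkbia is among the immediate early genes to be explained, and Klf9 was named for its large fall. Against this, the hormone is known to lower many NF-kB targets rather than raise them. An effect of the bacterium on colitis and T cell activation stays open and was not tested apart from these.

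Ribosomal protein genes were lower and chromatin regulator genes higher with Akkermansia. With offsets for gene length and GC content the ribosomal protein mean was -0.20 (SD 0.13, against -0.22 before) and 16 genes fell, so that trend as the whole cause is argued against, while the chromatin mean went from 0.18 to 0.12 with 5 rises at either setting, and the chromatin regulators list lost its call (0.0543), so such a trend stays open as part of that rise. The 10 most abundant genes held a share of the counts that was 0.19 percentage points below that of PBS (-0.19), too little for a few genes taking most of the counts. A different mix of cells or a different rate of proliferation stays open and was not tested.

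All 10 ways of parting the 6 libraries into 3 and 3 were fitted. The real one gave 1108 higher and 1253 lower genes with edgeR, and the highest of the others gave 0 (342 at an unadjusted p under 0.05), so 1 of 10 gave as many in either direction. For lists 1 of 10 gave as many as the real 23, and the others gave 8 to 17. Camera with the preset correlation thus called lists even in splits where edgeR called no gene. With 10 splits the share is never under 0.1, too few for a share under 0.05. Every other split also mixes libraries of both groups, so a real group difference would widen the spread within its groups. Few gene calls there were thus likely beforehand and do not measure what chance alone would give. Such splits can also keep part of a group difference, so their called lists are not all known to be false.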
